A study of Mus musculus with 16 samples.

How the data were processed

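Tail DNA of 1 male parent, 1 female parent and 6 F1 mice was hybridised against DNA of 1 reference male mouse on 16 two-colour Agilent arrays, 2 per mouse with Cy3 and Cy5 exchanged. Groups were taken from the labels. Per the file headers, the custom array had 1064 rows and 170 columns on mm9 and was read with Feature Extraction 10.7.1.1. The authors deposited processed red and green intensity values, background-subtracted and dye-normalized by a linear factor, the median intensity of each spot and of its background, and the log10 ratio of red over green. Median processed intensities lay between 906 and 951. The deposited value table holds log2 values. Set against the log10 ratios, with slopes of 1 and -1 by dye, it was reference over mouse on every array, shifted by up to 0.0225; the sources used here do not explain the shift.

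The ratio was log2 of the mouse's processed signal over that of the reference, with the direction taken from the dyes in the labels. Control spots and outlier spots were left out, 1030 probes with several spots were averaged, and each array was centred on its autosomal median. Another 182 missing values of single arrays were filled with the running median of 11 probes. The 2 arrays of a mouse were averaged.

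Each autosome of each mouse was segmented by optimal partitioning (PELT, squared error) with a penalty of 4 times the noise variance times the log of the number of probes, and values limited to 5 noise SD around the running median of 11 probes. A call needed at least 5 probes, a mean at least 0.3 from 0 and, in each dye orientation alone, a mean at least 0.2 from 0 in the same direction. Calls of one direction sharing a probe were merged, and the value of a mouse was the mean over the probes called in most mice; values of places are means over all their called probes. Positions are those of mm9. The stricter F1-only count asked that both parents lie within 0.15 of 0. Named regions were all strict F1-only regions, up to 15 regions of 1 parent and the 15 of the rest with the largest carrier mean, each ranked by distance from 0. These rules and tests were fixed before the data were examined, while the joining of regions within 50 kb and the limit of under 20 probes for short losses were chosen afterwards.

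Tested on simulated Gaussian noise with the SD of each mouse, which holds no trends along the genome, segmentation made 0 calls over 140145 probes. Steps of 0.4 added to real values of F1 replicates 2, 4 and 5 were recovered in 90.0% to 93.3% of 60 cases at 5 probes and 100% at 70 probes. Probe tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg) in 1 fit with 3 groups. In simulated data, shifts of 0.3 and 0.8 in the F1 against the reference were recovered at 85% and 99% of 100 probes each, with 11 false calls; for F1 against the parents the shares were 35% and 96%, with 7 false calls. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

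Both parents shared slide 1 and the F1 lay on 3 other slides, so slide entered only as a random block (correlation -0.087, estimated on every 10th probe). A negative correlation does not take out an effect shared by a slide, so this block is no adjustment for slide. Alternatives were the deposited value table, other centring, normexp, single dye orientations, other thresholds, penalties and probe minimums, breaks at gaps over 1 Mb, a running median of 501 probes subtracted, the median of the 8 mice subtracted, no dim probes, outlier spots kept, a fold minimum, means of 10 probes, arrays as separate samples and each F1 mouse left out. Leaving F1 mice out of the region counts was added after seeing the data. Normexp ran on median signals in place of the mean signals planned. The gene lists planned were not run, since the files pair no probe with a gene and no annotation of mm9 was used here, so regions are given by position alone.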

Results

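The series measured DNA copy number in tail DNA of 8 C57BL/6 mice of 1 family by two-colour comparative genomic hybridisation, in which labelled DNA of a mouse and of a reference compete for the same probes. The family consisted of 1 male parent, 1 female parent and 6 F1 offspring, and each was compared with the same reference male mouse. Each of the 8 mice was measured on 2 of the 16 arrays with the dyes exchanged, so the mean of both arrays counted as 1 mouse. The question of the design was whether offspring carry copy number changes that their parents lack. The labels conflict on the exposure of the father: the series title speaks of males exposed to gamma-rays at 0.05 mGy per day for 400 days, while the design text calls the male of this family non-irradiated. No other family was analysed here, so no value compares exposed with unexposed mice.

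The array held 140145 autosomal probes, 48 on X and 3 on Y, on mouse build mm9. Per the design text, its probes were placed densely around candidates from an earlier screen, so counts of regions and probes do not stand for the whole genome. Of the autosomal probes, 96.6% lay in 1950 dense patches with a median of 71 probes over 8309 bp. Between 98.1% and 99.7% of spots in either channel were well above background on each array. After both dye orientations were averaged, the noise SD between neighbouring probes ran from 0.047 in the female parent to 0.086 in F1 replicate 5 on the log2 scale. Across autosomal probes, the 2 arrays of a mouse, both turned to mouse over reference, correlated between -0.50 and -0.02, and arrays of different mice in one dye orientation correlated with medians of 0.57 (mouse in Cy5) and 0.54 (mouse in Cy3). These correlations run over probes, which are not independent replicates. The number of arrays limits the precision, and each parent is a single animal.

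X probes lay well above the reference in the female parent and in F1 replicates 5 and 6, and Y probes well below it in the same mice. The mean log2 ratio over X was 0.80 ± 0.08 in the female parent, 0.79 ± 0.13 in F1 replicate 5 and 0.76 ± 0.07 in F1 replicate 6 (SD between 2 dye orientations). It was -0.0010 ± 0.11 in the male parent and between -0.01 and 0.01 in F1 replicates 1 to 4. The 3 Y probes gave -1.89 ± 0.14 in the female parent, -1.80 ± 0.06 in F1 replicate 5 and -1.73 ± 0.15 in F1 replicate 6, against 0.03 ± 0.24 in the male parent and -0.05 to -0.01 in F1 replicates 1 to 4. With normexp background correction the Y means of the female parent and of F1 replicates 5 and 6 were -1.06, -1.09 and -0.99. Both parents had the X and Y levels that their labels call for against a male reference. F1 replicates 5 and 6 had levels close to those of the female parent, and F1 replicates 1 to 4 close to those of the male parent. The labels used here give no sex for the F1 mice.

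**Figure D1:**
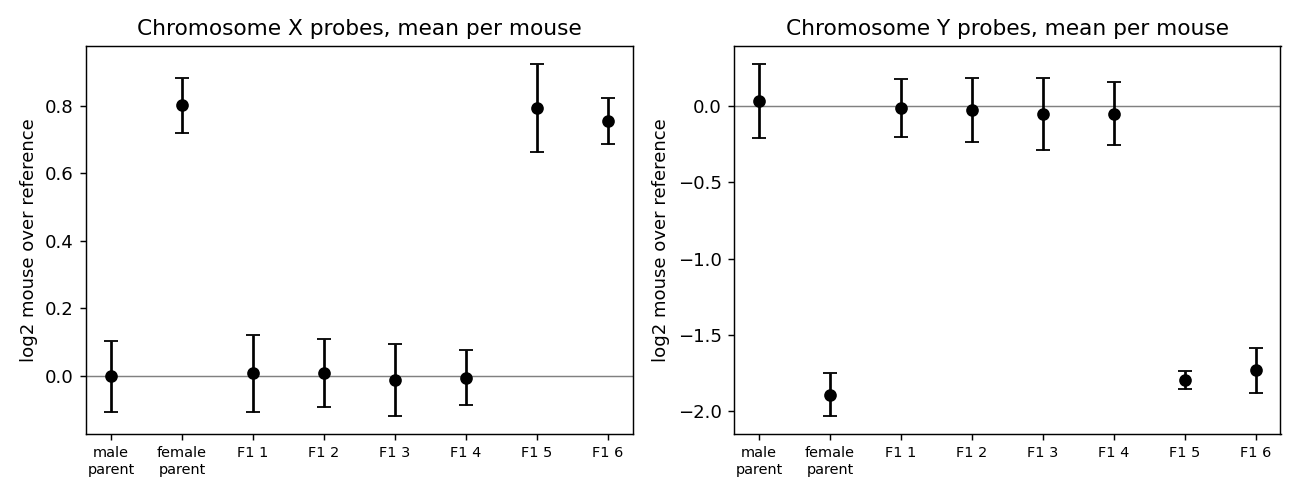
Mean log2 ratio of mouse over reference on the 48 X probes (left) and the 3 Y probes (right) for each of the 8 mice; points are means of 2 dye orientations and bars their SD. The female parent and F1 replicates 5 and 6 lie between 0.76 and 0.80 on X and between -1.89 and -1.73 on Y.

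The first comparison set regions called in 1 parent against the F1, to see which were found in offspring. A gain on chromosome 1 from 32580981 to 32600405 had a log2 ratio of 0.47 over 154 probes in the male parent. F1 replicates 2, 3, 4 and 6 carried it at 0.44, 0.49, 0.49 and 0.42, and the female parent (-0.02) and F1 replicates 1 (0.01) and 5 (0.02) did not. A loss on chromosome 12 from 114955700 to 114972279, over 131 probes, was called in the female parent at -0.37 and in F1 replicate 5 at -0.37, while the other mice lay between -0.02 and 0.01.

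Another 4 losses had similar depths in the female parent, F1 replicate 5 and F1 replicate 6. On chromosome 3 from 25417435 to 25456077 these mice had -1.80, -1.72 and -1.71 over 140 probes, and on chromosome 10 from 9789141 to 9789761 they had -1.09, -1.10 and -1.09 over 5 probes. On chromosome 14 from 61800954 to 61807847 they had -0.37, -0.38 and -0.40 over 36 probes. On chromosome 14 from 52021246 to 52021772 they had -0.53, -0.51 and -0.54 over 5 probes, where segmentation gave a called segment in the female parent alone although the means of F1 replicates 5 and 6 were as low. At these 4 places the male parent and F1 replicates 1 to 4 lay between -0.05 and 0.06.

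In all, 17 merged regions were called in 1 parent only, 11 in the female parent and 6 in the male parent. Each was tested against transmission to 50% of the offspring with a two-sided exact binomial test, and 0 passed Benjamini-Hochberg adjustment. The smallest p that 6 offspring allow is an exact 0.0312; the 5 regions without a called F1 carrier had it, with an adjusted p of 0.106. The chromosome 1 gain had 4 carriers of 6 (exact p = 0.688) and the chromosome 12 loss 1 of 6 (exact p = 0.219). At a call threshold of 0.5, 44 of 61 regions passed, and 52 of those 61 lay in a chromosome 4 gain from 101109089 to 101270967. With the median of the 8 mice subtracted from each probe, 20 of 31 passed. In both settings regions passed only because many shared the smallest p, which on its own cannot pass this adjustment. Regions can also be pieces of 1 place, so neither count is a number of separate departures from 50%.

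Of the 5 regions without a called F1 carrier, 1 was the chromosome 14 loss at 52021246, whose count of 0 carriers rests on the segmentation. The other 4 were short gains of the male parent, 2 of which were named after their values were seen. They lay on chromosome 3 at 140075792 (0.34), chromosome 11 at 89489153 (0.31), chromosome 12 at 46420602 (0.40) and chromosome 16 at 9525205 (0.39), and at all 4 an F1-only loss was called over the same probes. The chromosome 3 loss at 25417435 came out as 7 regions, of which 2 were counted as F1-only although the female parent had -1.70 and -1.20 over them. Joining regions of one direction within 50 kb, a grouping chosen after the calls had been seen, gave 61 places from 72 regions, 10 of them called in 1 parent.

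**Figure D2:**
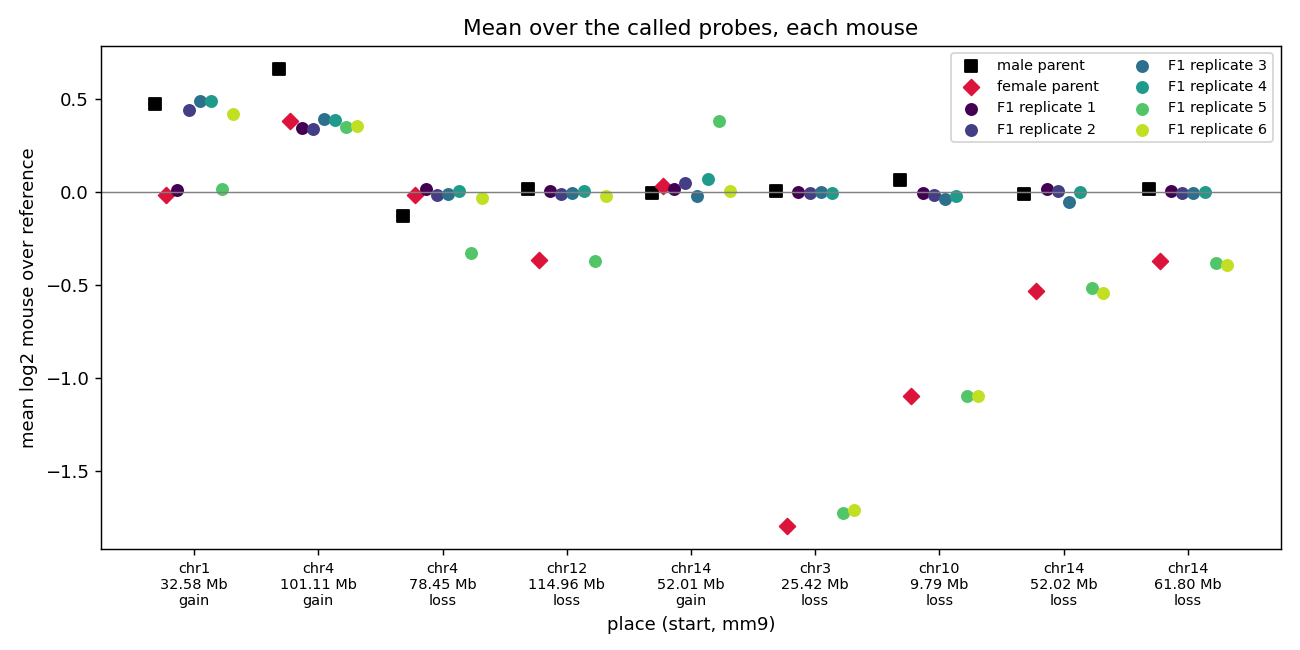
Mean log2 ratio of mouse over reference over the called probes at 9 places, 1 point per mouse, with the male parent as squares, the female parent as diamonds and the F1 as circles. At the chromosome 1 gain the male parent and 4 F1 mice lie between 0.42 and 0.49, and at the chromosome 3 loss the female parent and F1 replicates 5 and 6 lie between -1.80 and -1.71.

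A gain on chromosome 4 from 101109089 to 101270967, over 161879 bp and 1346 probes, was called in all 8 mice, so that the whole family differed from the reference mouse there. The F1 had 0.36 ± 0.02 (SD, n = 6) and the female parent 0.38. The male parent had 0.66, above all 6 F1 mice, which ran from 0.34 to 0.39, and its 2 dye orientations gave 0.69 and 0.63. Segmentation broke this gain into 4 regions, of which 3 were called in all 8 mice. The remaining region, from 101252624 to 101254844, was called in the male parent and F1 replicate 6 and was counted with the regions of 1 parent.

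The second comparison looked for regions called in at least 1 F1 mouse and in neither parent. The one with the most probes was a loss on chromosome 4 from 78452444 to 78463904 in F1 replicate 5, at -0.33 over 73 probes, with -0.42 and -0.23 in its 2 dye orientations. With normexp its mean over these probes was -0.296, short of the 0.3 call threshold. The male parent had -0.13 there, with -0.15 and -0.10, and the female parent and the other F1 mice lay between -0.03 and 0.02. F1 replicate 5 was -6.34 SD from the mean of the other 7 mice, at a place picked because this mouse was called there and neither parent was. The next probe after this loss lay 125720 bp away, so its far end was not measured. A gain on chromosome 14 from 52008865 to 52021220, beside the loss at 52021246, was called in F1 replicate 5 at 0.38 over 12 probes, while the other 7 mice lay between -0.02 and 0.07.

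**Figure D3:**
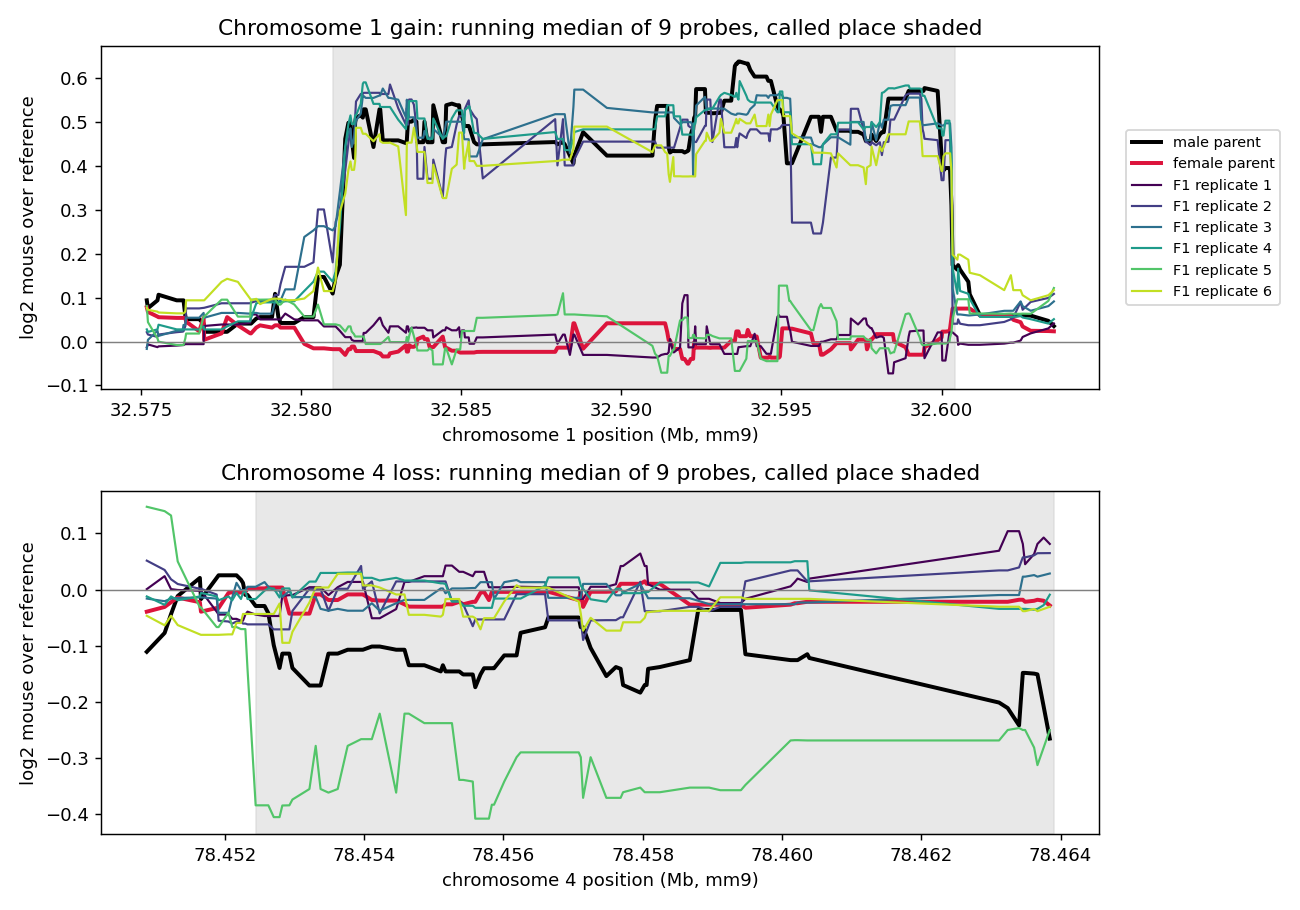
Running median of 9 probes of the log2 ratio of mouse over reference along a stretch of chromosome 1 (top) and of chromosome 4 (bottom), in Mb of mm9, 1 line per mouse, with the called place shaded. On chromosome 1 the male parent and F1 replicates 2, 3, 4 and 6 step up, and on chromosome 4 F1 replicate 5 has a mean of -0.33 and the male parent -0.13.

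Of the 72 merged regions, 52 were F1-only, 50 of them losses, and 47 of the 52 held at most 10 probes. They were called in F1 replicate 2 (40 regions), F1 replicate 6 (25), F1 replicate 5 (8) and F1 replicate 1 (1), and in F1 replicates 3 and 4 in 0. Without F1 replicate 2 the count was 30, with normexp 26 and with a minimum of 10 probes 10, while a minimum of 3 probes gave 98 and the arrays with the mouse in Cy5 alone 88.

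Only 9 of these regions passed the stricter rule that both parents lie within 0.15 of 0, and the count ran from 0 at a threshold of 0.5 to 32 with a minimum of 3 probes, with 28 and 21 from the arrays with the mouse in Cy5 or Cy3 alone and 24 at a threshold of 0.2. Besides the chromosome 4 loss and the chromosome 14 gain, they held 5 to 10 probes each. Losses had their lowest called value in F1 replicate 2 on chromosome 16 at 54922190 (-0.44), chromosome 14 at 112140206 (-0.41), chromosome 15 at 64589818 (-0.32) and chromosome 3 at 100490149 (-0.31). In F1 replicate 6 losses lay on chromosome 12 at 100882935 (-0.43) and chromosome 8 at 87470235 (-0.41), where F1 replicate 5, not called, had -0.94 and -0.85 with the mouse in Cy3 but 0.03 and -0.05 with the mouse in Cy5. A gain in F1 replicate 6 lay on chromosome 16 at 47333212 (0.32). The short strict losses are also among the 47 short F1-only losses described below. Their called mouse farthest from 0 lay only -1.48 to -2.14 SD from the mean of the other mice. Across the mice, their values correlated at 0.85 to 0.97 with the mean of the other strict losses. They were chosen by these same values, so neither measure is a test. Of 10000 random windows of as many probes in the same mouse, between 0.22% and 1.01% lay as far from 0 as these 9 regions; the windows include the gain shared by all mice.

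The F1-only losses of under 20 probes outside the chromosome 3 place formed 47 places of 195 to 1449 bp on 17 autosomes. Their medians differed from mouse to mouse, with -0.44 in F1 replicate 2, -0.33 in F1 replicate 6, -0.23 in F1 replicate 5, -0.15 in F1 replicate 1 and -0.04 in F1 replicate 3. F1 replicate 4 had 0.11, the female parent 0.09 and the male parent 0.21, and the male parent was above 0 at 44 of the 47 places. The rule for named regions gave, with the values of F1 replicate 2, losses on chromosome 2 at 98703221 (-0.75), chromosome 8 at 30866611 (-0.74), chromosome 14 at 87378935 (-0.64), chromosome 19 at 26171565 (-0.61) and chromosome 16 at 71859944 (-0.61). The same rule named losses on chromosome 9 at 38100945 (-0.59) and 90930820 (-0.55), chromosome 12 at 46420602 (-0.56) and 38416908 (-0.53), chromosome 4 at 54377332 (-0.55), chromosome 15 at 56597108 (-0.55), chromosome 6 at 103697093 (-0.53) and chromosome 18 at 23472926 (-0.51).

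**Figure D4:**
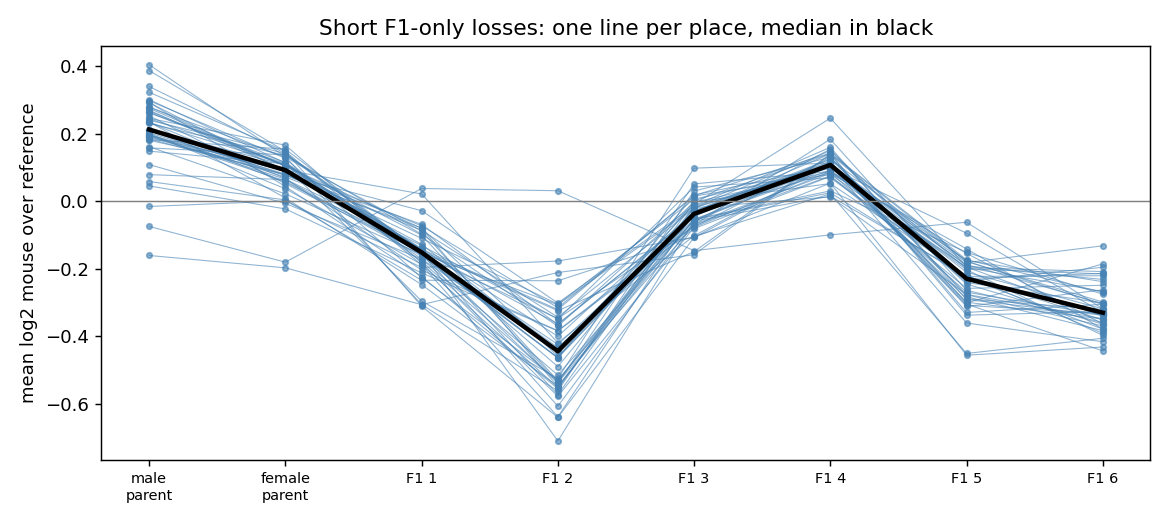
Mean log2 ratio of mouse over reference at the 47 short F1-only losses for each of the 8 mice, 1 thin line per place and the median over places in black. The medians run from -0.44 in F1 replicate 2 to 0.21 in the male parent.

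Single probes of the F1 differed from the reference mostly in the gain shared by all mice. With limma on the means per mouse, 1745 of 140145 autosomal probes passed an adjusted p of 0.05, 1454 higher and 291 lower. Of the higher ones, 1190 lay in the chromosome 4 gain at 101109089 and 24 in the chromosome 1 gain. Outside called regions lay 240 higher and 289 lower probes. Of these, 11 had a mean at least 0.3 from 0 and 29 lay next to another probe that passed. The reference is 1 mouse on every array, so these tests leave out its own spread. Arrays of 1 dye orientation gave 65259 probes with the mouse in Cy5 and 45400 with the mouse in Cy3. Within 1 orientation, dye effects of probes are not separated from the ratio. Arrays of different mice correlated there with medians of 0.57 and 0.54, against -0.24 for the 2 arrays of a mouse. These counts therefore do not stand for differences between the F1 and the reference. With the slide as a random block 2139 probes passed, and without F1 replicate 4 the count was 2669. The number of lower probes depended on single mice: it was 905 without F1 replicate 4, and with any other F1 mouse left out it ran from 75 (F1 replicate 2) to 161 (F1 replicate 5).

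Between F1 and parents 81 probes differed in limma, 28 higher and 53 lower in the F1, and 22 of the lower ones lay in the chromosome 4 gain, where the male parent was highest. The remaining 28 higher and 31 lower probes lay outside called regions, and 0 of the 81 were next to another such probe. Slide as a random block gave 123 probes, and leaving out F1 replicates 1, 2, 3 or 6 gave 50, 48, 51 or 49, of which 26, 26, 27 and 26 were lower. Parents and F1 shared no slide, so slide and group cannot be told apart by a fixed block. The random block does not adjust this comparison for slide either. Between the male and the female parent 61 probes differed, 34 higher and 27 lower in the male parent, 5 of them in the chromosome 4 gain and 0 next to another. Without dim probes the counts were 43 and 30. The balance of directions depended on the unit tested: between the parents, means of 10 probes gave 123 higher and 6 lower in the male parent and arrays as separate samples 282 and 0, and between F1 and parents these gave 12 higher and 129 lower, and 88 and 491. The arrays with the mouse in Cy3 alone gave 0 probes in limma for both comparisons, with 8307 and 3567 probes at an unadjusted p under 0.05. Those with the mouse in Cy5 alone gave 77 between F1 and parents and 64 between the parents. Each parent, a single mouse, was assumed to vary like the F1. In the fit of arrays as separate samples, the 2 arrays of a mouse counted almost as independent, so its larger counts do not rest on more animals.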

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

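All tests of explanations in this part were chosen after the values they use had been seen. In 43 sets of 6 F1 values, those of the named regions and 4 measures per mouse, 4 had 1 mouse far from the other 5 by Dixon's ratio, the gap to the nearest mouse over the whole range. Chance gives about 1 in 20 sets that were not chosen by their values, but most of these were regions chosen because mice were called there, so that share is no measure for them. All 4 concerned F1 replicate 5, the mouse with the highest noise SD (0.086), and 2 of them were parts of one chromosome 12 loss.

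The chromosome 4 loss at 78452444 had a ratio of 0.855, with -0.33 in F1 replicate 5 and -0.03 in the nearest F1 mouse, and -0.13 in the male parent. With normexp the mean of F1 replicate 5 there was -0.296, short of the 0.3 call threshold. Of all random windows of as many probes, 1.01% in F1 replicate 5 and 1.27% in the male parent lay as far from 0, a share that by itself leaves array noise open in F1 replicate 5; 83 and 116 of those windows touched the gain shared by all mice. With this place and places called in 2 or more mice left out, the shares were 0% and 0%. That definition was settled only after the shares above and those of another definition had been seen. In F1 replicate 5 its 0% decides nothing about noise of the arrays, since a window that far from 0 would most likely have been called. No other F1-only region held as many probes. In the male parent, whose -0.13 lay within the call threshold, the 0% argues against a chance low window. The male parent lay 0.20 higher than F1 replicate 5 (0.27 and 0.13 by dye orientation), which argues against an equal copy number state, and had 0.0024 at the chromosome 3 loss of F1 replicate 5, which argues against mixing of its DNA into the male parent's. A loss in part of the male parent's cells that F1 replicate 5 inherited remains possible, as do separate events, and neither was tested. The -0.33 of F1 replicate 5 lay much closer to 0 than loss of 1 of 2 copies in all its cells would give. The chromosome 12 loss, also called in the female parent, had -0.37 in this mouse.

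The chromosome 14 gain at 52008865 had a ratio of 0.776, with 0.38 in F1 replicate 5 and 0.07 in the nearest F1 mouse. The chromosome 12 loss had ratios of 0.917 at 114969115 and 0.884 at 114955700, with -0.54 and -0.35 in F1 replicate 5 and -0.04 in the nearest F1 mouse at both.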

How the results depend on the processing

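Leaving F1 mice out of the region counts was chosen after seeing the data. Means of called places were computed under normexp, the deposited value table, other centring, no dim probes and outlier spots kept, and none changed sign there. Under normexp, though, some strict F1-only regions fell short of 0.3. The chromosome 4 loss had -0.296 and the chromosome 16 gain at 47333212 had 0.289. Losses on chromosome 14 at 112140206 (-0.2855), chromosome 15 at 64589818 (-0.289) and chromosome 3 at 100490149 (-0.273) fell short too. The other strict regions stayed past 0.3. The deposited value table, centring on the mode, no centring and outlier spots kept left each count within 1.5 times its value. At least 98.1% of spots were well above background in each channel, but 80.1% of the probes of the short F1-only losses lay below the median signal, and leaving out 3371 dim probes lowered the probe counts for F1 against parents and between the parents. Where a cause is not given, the cause was not tested.

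With normexp the F1-only count was 26, the strict count 4 and the merged regions 45; X was 0.69 in the female parent and 0.65 in F1 replicate 6, and Y was -1.06 in the female parent, -1.09 in F1 replicate 5 and -0.99 in F1 replicate 6. With the mouse in Cy5 alone there were 235 calls, 112 merged, 88 F1-only and 28 strict regions, and 65259 probes for F1 against the reference. With the mouse in Cy3 alone there were 215 calls, 21 strict regions, 45400 probes for F1 against the reference, and 0 and 0 for F1 against the parents and male against female parent. Dye effects of probes are not separated from the ratio in either orientation alone.

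A threshold of 0.2 gave 111 merged, 24 strict and 34 one-parent regions. A threshold of 0.5 gave 144 calls, 0 regions in all 8 mice, 20 F1-only, 0 strict and 61 one-parent regions, with 44 past the transmission test; 52 of the 61 lay in the chromosome 4 gain, where the male parent alone had a mean past 0.5. A minimum of 3 probes gave 128 merged, 98 F1-only, 32 strict and 27 one-parent regions. A minimum of 10 probes gave 263 calls, 21 merged, 10 F1-only, 3 strict and 8 one-parent regions, since shorter ones cannot be called. A penalty factor of 2 gave 669 calls and 21 regions in all 8 mice, and a factor of 8 gave 194 calls, 1 region in all 8 mice and 5 strict regions. Breaks at gaps over 1 Mb gave 5 regions in all 8 mice. With the running median subtracted there were 166 calls, 1 region in all 8 mice and 33 one-parent regions. With the median of the 8 mice subtracted there were 109 calls, 34 F1-only, 3 strict and 31 one-parent regions, with 20 past the transmission test, and 0 in all 8 mice, since a shared gain is removed.

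For F1 against the reference, F1 against the parents and male against female parent, means of 10 probes gave 244, 141 and 129, counted in bins (159, 12 and 123 higher), and arrays as separate samples gave 3735, 579 and 282 (2338, 88 and 282 higher). In the fit of arrays, the 2 arrays of a mouse counted almost as independent. A minimum of 0.3 gave 887 probes for F1 against the reference, and slide as a random block 123 for F1 against the parents. Without dim probes 43 probes differed between F1 and parents and 30 between the parents. With each F1 mouse left out in turn, F1-only regions ran from 30 to 52, regions in all remaining mice from 3 to 8, probes for F1 against the reference from 1317 to 2669 and for F1 against the parents from 48 to 106. Of the means of single places, normexp moved 20, leaving out dim probes 2 and centring on the mode 1 by more than their spread.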

Other observations

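All tests in this part were chosen after the values had been seen except that of dim signal, which was run after the short losses were known to hold mostly dim probes.

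Most of the 47 short F1-only losses were lowest in the same mice, though not all: on chromosome 4 at 124095982 F1 replicate 2 had 0.03 and the male parent -0.07. The male parent, in which none of these losses was called, was above 0.1 at 87.2% of the places against 3.17% of random windows of as many probes, not matched on signal, and its median of 0.21 argues against separate new losses in the F1 as the whole source. F1 replicates 3 and 4, of one slide and scan day and not called at any of these places, differed by a median of 0.15, with F1 replicate 4 higher at 47 of 47, which argues against slide or scan day as the whole source. Of the probes 80.1% lay below the median signal, yet F1 replicate 2 had a mean of 0.0003 over the tenth of autosomal probes with the lowest signal, called places left out, which argues only against a trend of all dim probes. One trend over the mice shared by unlinked sequences remains a candidate explanation, and neither its origin nor a biological one was tested.

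The losses on chromosomes 3, 10 and 14 had their low values in the female parent and F1 replicates 5 and 6, the mice with low Y probes. An autosomal deletion passed on by the female parent is argued against on chromosome 3. That mouse had -1.80 there, lower than the loss of 1 copy would give, and the highest F1 mean was -0.0005. On chromosome 10 arrays of the 3 mice lay between -1.11 and -1.08, and the highest F1 mean was -0.0073. Arrays of the other mice there ran from -0.05 to 0.08. This depth, over 5 probes and -1.03 with normexp, is close to what loss of 1 copy would give, so these values decide nothing on chromosome 10. On chromosomes 3 and 10, at most 0.07% of random windows in any of these mice lay as far from 0. The places were called for their depth, so this share decides nothing about noise of the arrays. Every array of the 3 mice was at -1.70 or below on chromosome 3 and at -1.08 or below on chromosome 10. That argues against noise of single arrays there. On chromosome 14 at 52021246 the array closest to 0 in F1 replicates 5 and 6, not called there, had -0.48. That argues against noise of single arrays only, at a place picked for its low means. The window shares there were 0.14% in the female parent, 0.12% in F1 replicate 5 and 0.10% in F1 replicate 6. At 61800954 the share reached 0.78%, which decides nothing. Sequence also held by the Y chromosome of the male reference may account for these losses: of the 5 losses called in the female parent, 4 followed the Y probes and the chromosome 12 loss did not. No sequence was compared and the places were picked for the pattern. For the chromosome 10 loss, such sequence cannot be told apart from a deletion in 1 copy. The chromosome 14 losses had -0.37 to -0.40 and -0.51 to -0.54 in the 3 mice. That is closer to 0 than loss of 1 of 2 copies in all cells would give, and its source was not tested.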
